A study of Escherichia coli with 15 samples.

How the data were processed

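RNA of EPEC strain Deng from 3 arms (saline, 2 µg/ml and 4 µg/ml ciprofloxacin) at 0, 45, 90, 135 and 180 min was labelled with Cy3 and hybridised to 15 Agilent arrays, per the labels. Each array's file holds the spot intensity of 60081 spots as written by Agilent Feature Extraction 10.7.1.1, per the file headers. The deposited intensity used here is the processed signal, which the scanner software had corrected for background, per the file headers. It is on a linear scale and is not normalized between arrays. The authors' value table of the series holds the same intensity values, with a largest relative difference of 0, so its scale is linear and no centring had been applied. How the authors normalized or tested the values is not given in the sources used here.

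The main values were log2 of the processed signal minus each array's 75th percentile over 58762 non-control spots. Spots marked as outliers were left out where other spots of the probe remained, and the spots of a probe, 10 to 12 for each, were averaged. A tag with 2 probes (49 tags) was represented by the brighter. Tags entered the tests when well above background on at least 4 of the 15 arrays, which left 4641 of 4856. No genome or annotation of this strain was used here, and 0 tags matched the gene table at hand, so the 27 gene lists chosen before the data were examined had 0 members on the array by name, and the list tests could not be run. Classes of tags, chosen after the data were seen, were tested by the same methods. The rule for named genes took called genes with a symbol and a set of SOS, gyrase, efflux and porin genes, and none could be read. At most 2 tags that were higher and 2 that were lower are named, chosen after their values were seen: the 2 largest of those called at 4 µg/ml over 45 and 90 min, and the 2 with the most negative largest value over the 6 contrasts of drug and saline on arrays of 1 kind, among 3201 tags well above background on all 15 arrays. This rule was changed once after values had been seen: an earlier one, the largest smallest difference over the 6 contrasts, had named another pair of higher tags.

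Tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Arms were compared as mean differences over the 12 later arrays with time point as a block, and slopes per hour were fitted per arm over all 15 arrays. The 3 arms shared one estimate of the spread. Classes of tags were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Differences of a single tag at a single time point compare 1 array with 1 and were not tested. Sets from 45 min were compared with 10000 random lists matched on mean level. A wave of 1 period over the numbers of the tags was tested by permuting blocks of 50 tags 9999 times, and differences between windows of tags have 95% intervals from 999 bootstrap draws of blocks.

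The precision is limited by the number of arrays and, in fits without the kind of array as a term, by the difference between the kinds. In comparisons of arms that difference cannot be separated from a change of 4 µg/ml between 135 and 180 min. The fit was tested on simulated data for 2 µg/ml against saline, with 200 of 4641 tags changed. Without the kind of array as a term, the simulation recovered 0% of 50 tags changed by 1 log2 unit, 16% changed by 2, 44% changed by 3 and 50% changed by 4, with 1 false call. With the term it recovered 46%, 96%, 96% and 100%, with 12 false calls. The simulated values contained the kind of array and took their noise from the fit with that term, so the gain from the term was built in. They held no change of an arm between time points. Simulated noise was drawn independently for each tag, which real arrays need not follow. The recovery with the term is therefore a best case. A planted trend along tag numbers of 0.3 log2 units was found at 0.29.

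Alternatives set before the data were examined were quantile normalization, normexp background correction with an offset of 50, another base of the percentile, 2 other filters on dim probes, the authors' value table, the mean of probes, the slide as a block, leaving out each array and each time point, the spread of the 0 min arrays alone, each arm's 0 min array as baseline, fits of only the arms compared, no time block, and a 2-fold minimum. For normexp the median spot signal was used, since the files hold no mean signal. The kind of array as a term, the restriction to time points with arrays of 1 kind, the control-probe signal as a covariate and the removal of tags that follow the control probes were added after the data were seen, as were the tests of classes of tags, of the 45 min sets and of tag order. The planned tests called 0 tags, so each positive result came from a choice made after the data were seen. Several correlation thresholds, runs of tags and blocks of 25 tags were looked at before the thresholds of 0.95 and 0.9 and the blocks of 50 were fixed. A separate pattern on the 2 µg/ml 90 min array was tested with 2 explanations, nonspecific signal and an untreated sample, the comparison array of the second was changed once, and the pattern was then dropped for that of the control probes. The kinds were divided at an rRNA share of 60%, which fell in the gap between 42.3 and 76.9%.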

Results

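The study followed the transcriptional response of the enteropathogenic Escherichia coli (EPEC) strain Deng to ciprofloxacin, a fluoroquinolone that inhibits DNA gyrase and topoisomerase IV. Cultures received saline or ciprofloxacin at 2 or 4 µg/ml. RNA was taken at 0, 45, 90, 135 and 180 min and hybridised to 1-colour arrays, which gave 15 arrays in 3 arms of 5 time points. Each arm and time point had 1 array, so no value of a single time point has a replicate error. The labels do not say that the time points of an arm came from separate cultures, so p-values over time points measure how steadily an arm differed from another across time points and not the spread between cultures.

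The arrays carried 4905 probes for 4856 locus tags, and 4641 tags entered the comparisons. The files identify genes by locus tag and do not pair the tags with gene names, and 0 of the tags matched the gene table used here. The SOS, topoisomerase, efflux and other gene lists chosen before the data were examined therefore had 0 members that could be read, and groups of genes are described by the class written in the tag. These classes are 4405 plainly numbered tags, 101 tags marked P1, 5 marked P2, 65 marked ncR, 52 tRNA tags and 11 rRNA tags.

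The arrays differed in the share of signal that fell on rRNA probes. On 10 arrays the rRNA tags held 76.9 to 91.6% of the summed signal, and on the other 5 arrays they held 22.8 to 42.3%. These 5 arrays were 2 and 4 µg/ml at 0 min, saline and 2 µg/ml at 135 min, and 4 µg/ml at 180 min. Their log2 signal spanned 13.5 to 15.6 units between percentiles 1 and 99, against 8.36 to 10.4 units on the others. They are called wide-range arrays here, and the other 10 rRNA-dominated arrays. The division explained 70.2% of the variance between arrays, against 42.1% for time point, 6.27% for arm and 4.10% for slide. Arrays of different kinds had rank correlations over tags of 0.334 to 0.788, pairs of wide-range arrays had 0.867 to 0.983, and pairs of rRNA-dominated arrays had 0.496 to 0.988, a range that overlaps that of different kinds. Tags are not independent replicates in these correlations. Of the later time points, 2 µg/ml was compared with saline on arrays of 1 kind at 45, 90, 135 and 180 min, and 4 µg/ml with saline only at 45 and 90 min.

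**Figure D1:**
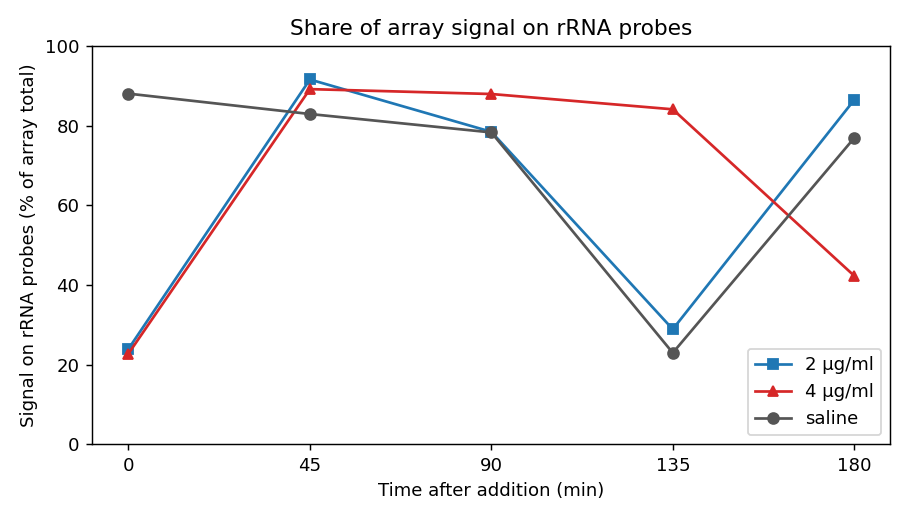
Share of each array's summed signal on rRNA probes (percent, vertical axis) against time (min, horizontal axis) for saline, 2 µg/ml and 4 µg/ml, with 1 array per point. The 5 arrays at 22.8 to 42.3% come from all 3 arms and from 0, 135 and 180 min.

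The first comparison asked which transcripts differed between 2 µg/ml ciprofloxacin and saline over 45 to 180 min. rRNA tags had a median log2 difference of 0.83 and were higher in 11 of 11, and tRNA tags had a median of 0.32 and were higher in 36 of 52. ncR tags had a median of 0.014, with 34 of 65 higher. By time point the rRNA tags' median difference was 1.53 at 45 min, -0.16 at 90 min, 0.63 at 135 min and 1.32 at 180 min, and the tRNA tags' was 0.69, -0.79, 0.44 and 0.79. At 0 min, where the arrays were of different kinds, the rRNA median was -3.25 and the tRNA median 0.89, with 37 of 52 tRNA tags higher, so the tRNA difference at 0 min was at least as large as those later. The tag E2348C_0674 was higher by 2.75, 0.17, 4.68 and 2.66 log2 units at the 4 later times, against 0.05 at 0 min. E2348C_1778 was lower at each later time, with log2 differences of -2.70, -1.88, -0.95 and -2.25, but it was also at -5.67 at 0 min. E2348C_1759 had -1.53, -1.12, -1.25 and -2.19 at the later times and -0.22 at 0 min. Over the 4 later times E2348C_0674 was higher by 2.56 ± 1.26 (SE), E2348C_1778 was at -1.95 ± 1.09 and E2348C_1759 at -1.52 ± 0.64, and limma called none of them at 2 µg/ml. Without the 2 µg/ml array at 135 min the mean of E2348C_0674 was 1.38, and without the saline array at 180 min those of E2348C_1778 and E2348C_1759 were -1.17 and -0.99. These tags, and those of the next comparison, were chosen after their values were seen.

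Camera with a preset correlation of 0.01 called rRNA (adjusted p = 1.09e-10) and tRNA tags (adjusted p = 0.00075) higher at 2 µg/ml, together with P1 tags (adjusted p = 0.0225) and P2 tags (adjusted p = 0.048). With an estimated correlation none of these calls held (adjusted p = 0.386 for rRNA and 0.628 for each of tRNA, P1 and P2). After quantile normalization the rRNA tags' mean difference was 0.0060, against 0.79 without it, and that of tRNA tags 0.071, against 0.21. The rRNA tags' median level lay 8.88 to 12.7 log2 units above the 75th percentile of each array. Quantile normalization gives the brightest spots nearly the same values on all arrays, so it cannot test the rRNA difference. The P1 and P2 calls also ended with the slide as a block (adjusted p = 0.133 for both). At 45, 90, 135 and 180 min the P1 median was 0.02, 0.26, -0.09 and 0.05, and the P2 median 0.59, 2.07, -0.06 and -0.28. The rRNA probes' median signal lay between 18.85 and 19.43 log2 units on every array, close to the scanner's saturation value of 19.57, and their differences are relative to each array's 75th percentile. Before scaling, this signal was 19.43 at 2 µg/ml against 19.19 in saline at 45 min, and 19.16 against 18.85 at 135 min. It was lower than in saline at 90 min (19.02 against 19.38) and 180 min (19.16 against 19.39). Over single tags, limma called 0 of 4641 at an adjusted p under 0.05, with 41 at an unadjusted p under 0.05. Leaving out 1 array moved this unadjusted count from 4, without 2 µg/ml at 45 min, to 148, without 4 µg/ml at 180 min, an array that enters only through the shared spread. The median standard error of a difference was 0.73 log2 units and the median 95% half-width 1.66.

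With the kind of array added as a term, a choice made after the data were seen, the median standard error was 0.27 log2 units. Among the later arrays, kinds differed within a time point only at 135 and 180 min, where 4 µg/ml was the odd array. With time point as a block, the term thus cannot be separated from a change of 4 µg/ml between those times. The smaller standard error and the counts with the term may rest on either. With the term limma called 0 tags again at 2 µg/ml, with 710 at an unadjusted p under 0.05 and a lowest adjusted p of 0.178. Of these 710, 179 were higher and 531 lower. A planned fit of only the 2 µg/ml and saline arms also called 0 tags, with 617 at an unadjusted p under 0.05. By chance 232 are expected, though tags are not independent. That fit holds no 4 µg/ml array and no difference of kind within a time point, so its count rests on neither. The sign of the median-centred difference was the same at all 4 later times for 1046 of 4641 tags, or 22.5%, where independent signs give 12.5%. No other pattern of signs over the 4 time points gave more than 810. With only 8 possible patterns, the smallest p this exact comparison allows is 0.125.

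The second comparison asked the same question of 4 µg/ml. The rRNA tags had a median log2 difference from saline of 1.18 and were higher in 11 of 11, and the tRNA tags had 0.57 and were higher in 43 of 52. On arrays of 1 kind, the rRNA median was 1.06 at 45 min and 1.22 at 90 min, and the tRNA median 0.56 and 0.63. Before scaling, the rRNA probes were not brighter at 4 µg/ml. Their median log2 signal was 19.18 against 19.19 in saline at 45 min, and 19.08 against 19.38 at 90 min. The 75th percentile of signal was 128 against 250 and 139 against 381, so the rRNA difference came from this divisor. At 0 min, between different kinds, the rRNA median was -3.58 and the tRNA median 1.31, with 40 of 52 tRNA tags higher. Camera called rRNA (adjusted p = 5.52e-17), tRNA (adjusted p = 1.83e-11) and P1 tags (adjusted p = 0.00569) higher. With an estimated correlation the adjusted p was 0.171, 0.345 and 0.568. The P1 median was -0.22 at 45 min, with 34 of 101 higher, and 0.25 at 90 min. Between arrays of different kinds the P1 median was 3.68 at 135 min and -2.99 at 180 min, and the tRNA median -0.53 and 1.61. After quantile normalization the rRNA tags' mean difference was 0.015, against 1.13 without it, which again cannot test the rRNA difference. Over all later times limma called 0 of 4641 tags, with 62 at an unadjusted p under 0.05, of which 23 were higher and 39 lower. The unadjusted count rested on single arrays: it was 488 without the 4 µg/ml array at 135 min, 113 without that at 180 min and 23 without the saline array at 180 min, and 0 tags were called in each. With the kind of array as a term limma called 0, with 815 at an unadjusted p under 0.05, of which 259 were higher and 556 lower, and a lowest adjusted p of 0.121. Here too the term cannot be separated from a change of 4 µg/ml between 135 and 180 min.

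At 45 and 90 min alone, where 4 µg/ml and saline were both measured on rRNA-dominated arrays, limma called 4 tags, all higher than saline. This restriction was chosen after the data were seen, and the fit had 1 residual degree of freedom beside 7.39 borrowed from all tags. E2348C_0674 was higher by 3.20 ± 0.35 log2 units (SE) with a limma adjusted p of 0.0304. Its difference was 3.72 at 45 min and 2.68 at 90 min, against -0.36 at 0 min. The 0 min arrays of these arms were of different kinds, so they give no baseline within 1 kind. E2348C_2532 was higher by 2.93 ± 0.34 (limma adjusted p = 0.0304), with 3.38 at 45 min, 2.49 at 90 min and -1.18 at 0 min. The other 2 called tags were higher by 2.86 and 2.77. Between arrays of different kinds, E2348C_0674 was at 0.81 at 135 min and 7.54 at 180 min, and E2348C_2532 at 0.45 and 6.18. Over all 4 later times the mean of E2348C_0674 was 3.69, or 2.42 without the 4 µg/ml array at 180 min, and that of E2348C_2532 was 3.12, and limma called neither over those times. At 2 µg/ml, E2348C_2532 had differences of 2.38, -0.16, 3.38 and 2.56 at 45, 90, 135 and 180 min, so its value at 90 min was near saline, as was that of E2348C_0674. E2348C_1778 and E2348C_1759 had -1.20 and -1.09 at 45 min and -1.14 and -0.91 at 90 min under 4 µg/ml. Between arrays of different kinds, E2348C_1778 and E2348C_1759 were higher than saline at 135 min, by 1.41 and 0.12, and at -6.12 and -3.99 at 180 min. Their mean differences over all 4 later times were -1.76 and -1.47, which rest on the 4 µg/ml array at 180 min: without it they were -0.36 and -0.74. Without the saline array at 180 min they were -0.99 and -0.94, and without the 4 µg/ml array at 135 min that of E2348C_1778 was -2.65. limma called neither.

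The third comparison set 4 against 2 µg/ml. rRNA tags had a median difference of 0.35 and were higher in 11 of 11, and tRNA tags had 0.31 and were higher in 47 of 52. Camera called both (adjusted p = 6.37e-07 and 6.34e-12), and with an estimated correlation the adjusted p was 0.381 for both. The direction was not steady over time points on arrays of 1 kind, since the rRNA median was -0.52 at 45 min and 1.39 at 90 min. The tRNA median was -0.16 and 1.61. At 0 min, also on arrays of 1 kind, the rRNA median was -0.31, with 0 of 11 higher. The tRNA median was already 0.42 at 0 min, with 48 of 52 higher. limma called 0 of 4641 tags, with 1 at an unadjusted p under 0.05, and 46 with the kind of array as a term, where 232 are expected by chance. Without the 4 µg/ml array at 135 min limma called 0, with 587 at an unadjusted p under 0.05, and without that at 180 min it called 0, with 135.

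The mean differences of the 2 doses from saline correlated over tags at 0.863. Both use the same saline arrays, and simulated unchanged arms gave 0.501. The covariance was 0.222, below the 0.422 simulated with the spread of the fit without the kind of array and above the 0.0587 simulated with that term. When 2 µg/ml at 135 and 180 min was set beside 4 µg/ml at 45 and 90 min, contrasts that share no array and compare arrays of 1 kind, the correlation was 0.452 and the covariance 0.094. Tags are not independent replicates in these correlations either. With saline split as planned, the correlation was 0.610 for 2 µg/ml at 45 and 135 min against 4 µg/ml at 90 and 180 min, and 0.496 for the reverse. Over all 4 later times limma called no tag at either dose, so the count called at both was 0 and independent lists also give 0, beside 41 and 62 at an unadjusted p under 0.05.

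Tags that differed from saline early were then read at later times. At 45 min, 156 tags were at least 2-fold higher than saline at both doses, where independent lists give 14.7, and 54 were at least 2-fold lower at both, where independent lists give 20.6. Both doses were compared with the same saline array, so the 2 lists were not independent. The higher set held 132 numbered tags, 10 tRNA, 6 rRNA, 6 ncR, 1 P1 and 1 P2 tag, and the lower set held 53 numbered tags and 1 ncR tag. The sets were formed after the data were seen and were then read on the other arrays, with each difference centred on the median of all tags.

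The higher set lay above saline on the later drug arrays, compared within 1 kind, except on the 2 µg/ml array at 90 min. Its median log2 difference was 0.48 for 2 µg/ml at 135 min, with 121 of 156 tags higher, and 0.46 at 180 min, with 126 higher. For 4 µg/ml it was 0.53 at 90 min, with 148 higher. Against saline arrays of the same kind at other times, it was 0.47 for 4 µg/ml at 135 min and 1.20 at 180 min. The 1.20 was read against saline at 135 min, and the 0 min arrays gave 1.16 for 2 µg/ml, with 125 of 156 tags higher, and 0.28 for 4 µg/ml against that same array. Each of these medians lay above all 10000 random lists matched on mean level. So did that of saline at 90 min relative to 180 min, at 0.18, so a place above all random lists was not particular to later drug arrays. The exception was 2 µg/ml at 90 min, with a median of -0.20 and 56 of 156 tags higher, which was still above 99.6% of random lists, whose median was -0.37. In saline the same set was at 1.79 on the 0 min array relative to the 180 min array, with 139 of 156 tags higher. The lower set had a median of -0.27 for 2 µg/ml at 135 min and -0.62 at 180 min, and -0.55 for 4 µg/ml at 90 min. It was also at -0.27 for 2 µg/ml at 0 min against saline at 135 min, with 30 of 54 tags lower, against 38 at 135 min. It was at -1.05 and -0.46 for 4 µg/ml at 135 and 180 min against saline at other times, while 4 µg/ml at 0 min was at -0.73 against the same saline array as 180 min, with 43 of 54 tags lower. In saline alone the lower set was at 0.47 at 90 min relative to 180 min. It was at -0.75 for 2 µg/ml at 90 min, with 52 of 54 tags lower. Quantile normalization and normexp kept the sign of each of these medians but moved their size. For the higher set, 2 µg/ml at 135 min was at 0.16 with quantile normalization and 0.26 with normexp, and 2 µg/ml at 180 min was at 0.19 with normexp. With normexp, 4 µg/ml was at 0.28 at 90 min and 0.32 at 135 min. At 180 min it was at 0.56 with normexp and 0.71 with quantile normalization. Quantile normalization also moved 2 µg/ml at 90 min to -0.32, 2 µg/ml at 0 min to 0.48, 4 µg/ml at 0 min to 0.44 and saline at 90 min to 0.39. Normexp moved 4 µg/ml at 0 min to 0.52 and saline at 0 min to 0.93. For the lower set, quantile normalization moved 4 µg/ml to -0.95 at 90 min, -1.70 at 135 min and -0.28 at 180 min, 2 µg/ml to -1.21 at 90 min, and saline at 90 min relative to 180 min to 0.77. Both scalings moved 2 µg/ml at 0 min to -0.15. These differences describe single arrays and were not tested against replicates.

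**Figure D2:**
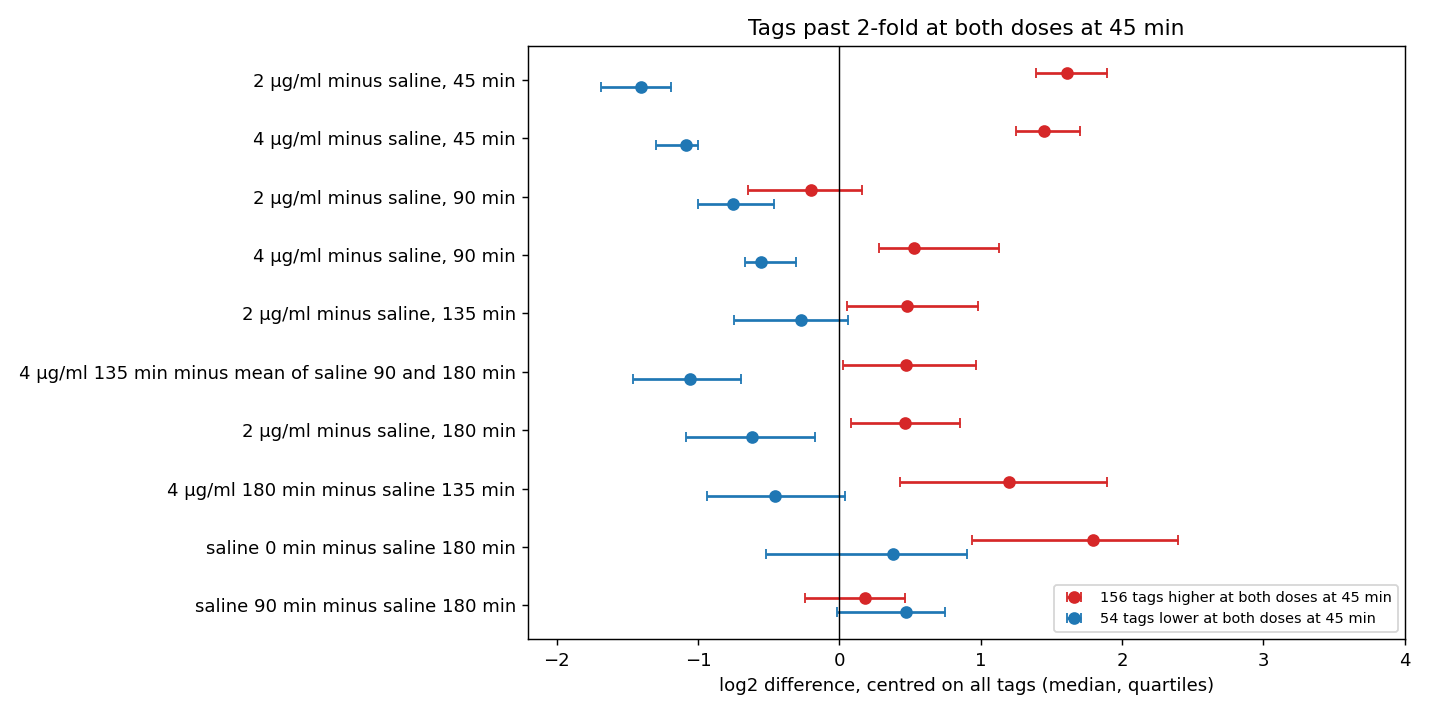
Median log2 difference (points) and quartiles over tags (bars) of the 156 tags that were at least 2-fold higher and the 54 that were at least 2-fold lower than saline at both doses at 45 min, for contrasts between arrays of 1 kind, centred on all tags. The 45 min contrasts define both sets. In the other drug contrasts shown, the higher set's median is above 0 except for 2 µg/ml at 90 min, where it is -0.20. It is at 1.79 in saline at 0 min relative to 180 min. The 0 min drug arrays against saline at 135 min, with medians of 1.16 for 2 µg/ml and 0.28 for 4 µg/ml, are not shown.

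Counts of tags at least 2-fold from saline at a single time point followed the kinds of array. On arrays of 1 kind, 2 µg/ml had 837 such tags at 45 min (362 higher, 475 lower), 1737 at 90 min (918 higher, 819 lower), 344 at 135 min (171 higher, 173 lower) and 313 at 180 min (101 higher, 212 lower). For 4 µg/ml there were 389 at 45 min (188 higher, 201 lower) and 505 at 90 min (399 higher, 106 lower). The balance of higher and lower tags depended on the scaling and the filter: for 4 µg/ml at 45 min normexp gave 88 higher and 32 lower. Between arrays of different kinds, 4 µg/ml had 3524 at 135 min and 3571 at 180 min. The background at 0 min was also between different kinds and was 3365 tags for 2 µg/ml and 2749 for 4 µg/ml. Between the saline arrays at 45 and 90 min, which lay on different slides, the count was 42. Their rank correlation of 0.988 was the highest of all pairs of arrays. Other pairs of rRNA-dominated saline arrays had more such tags: 210 between 45 and 180 min and 418 between 90 and 180 min. The saline array at 0 min had 1225, 1244 and 1594 against those at 45, 90 and 180 min. On arrays of 1 kind, counts as large as those under the drug thus also arose between saline arrays, except for the 1737 of 2 µg/ml at 90 min. The saline counts above 418 all involved the 0 min array.

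Part of these counts came from tags whose signal followed the control probes of the array. Over the 15 arrays, 455 tags had a log2 signal that correlated above 0.95 with the median of the control probes, and 737 correlated above 0.9. The latter were 34 of 101 P1 tags, 3 of 5 P2 tags, 695 of 4405 numbered tags, 4 of 65 ncR tags, 0 of 52 tRNA tags and 0 of 11 rRNA tags. Without the 737, 2 µg/ml at 90 min had 1053 tags past 2-fold (234 higher, 819 lower), and 4 µg/ml at 90 min had 229 (123 higher, 106 lower). The other counts on arrays of 1 kind were then 771, 323 and 310 for 2 µg/ml at 45, 135 and 180 min. For 4 µg/ml at 45 min the count was 277. At 2 µg/ml these tags thus mattered chiefly at 90 min. The 4 tags named above were well above background on all 15 arrays.

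**Figure D3:**
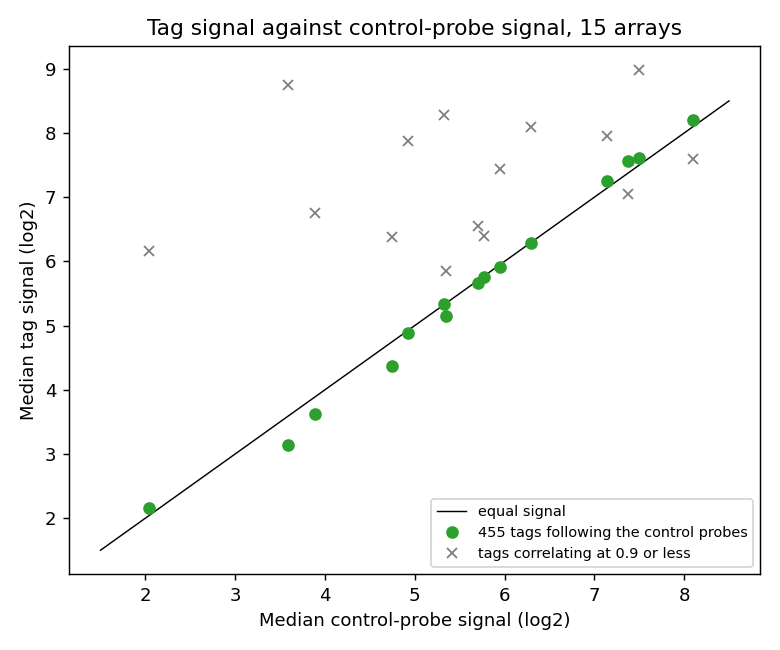
Median log2 signal of tags on each of the 15 arrays (vertical axis) against the median log2 signal of the control probes on the same array (horizontal axis). The median of the 455 tags that correlated above 0.95 lies within 0.45 log2 units of the line of equal signal on every array. The median of the tags that correlated at 0.9 or less (crosses) does not follow it. Single tags are not shown.

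The last comparison asked how levels moved with time. limma called 0 of 4641 tags for a slope over time in saline, with 14 at an unadjusted p under 0.05. For the difference of slopes from saline it called 0 at 2 µg/ml and 0 at 4 µg/ml, with 20 and 35 at an unadjusted p under 0.05. Leaving out 1 array also called 0, and moved the unadjusted counts from 1 (without saline at 0 min) to 56 (without saline at 180 min) for the saline slope. For 2 µg/ml they moved from 0 (without the saline or the 2 µg/ml array at 0 min) to 61 (without 2 µg/ml at 45 min), and for 4 µg/ml from 9 (without 4 µg/ml at 0 min) to 49 (without 4 µg/ml at 45 min). The median standard error was 0.53 log2 units per hour for the saline slope and 0.74 for each difference. With the kind of array as a term, the counts called were again 0, and those at an unadjusted p under 0.05 were 361, 210 and 379, where 232 are expected by chance.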

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

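All tests in this part were chosen after the results were seen, and the bounds that decide them were also set then. The control probes (22 E1A and ERCC probes, which the planned comparisons did not use) gave signal above the negative controls by 5.90 log2 units on the 2 µg/ml 90 min array, the highest of the 15, and by 0.21 on the saline 0 min array, the lowest. The 4 µg/ml 135 min array had 5.37 and the 4 µg/ml 0 min array 5.28. No label says whether control RNA was added.

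The signal of 455 tags followed these control probes. Their median lay within 0.449 log2 units of the control probes' median on every array, and no tag correlated above 0.95 in 100 permutations of the arrays. Drug exposure was tested on 749 tags chosen by the same correlation on the 10 drug arrays alone. Over the 5 saline arrays, which had no part in this choice, their median signal ranged over 4.90 log2 units, against 5.10 for the control probes and 2.25 for tags that correlated at 0.9 or less. It lay within 0.209 of the control probes on each saline array. This argues against drug exposure as the whole cause. The test was added after the medians of the 455 tags on the saline arrays had been seen. The tags past the lower correlation of 0.9 also lay in runs of neighbouring tag numbers, the longest with 17 tags (1816 to 1832) against at most 9 in permutations of the tags. A candidate explanation is that these probes found no matching transcript in strain Deng and read nonspecific signal. It cannot be told apart from the alternatives, because the tags were selected by their correlation with the same control probes, missing and silent genes look alike, and no sequence of the strain was used. That dim probes behave so in general also stays open. Of 823 tags with a mean signal below the median of the 455, 11.3% correlated under 0.5 with the control probes and 49.9% above 0.9. The 823 include those of the 455 that lay below that median, so both shares were partly set by the selection. The bound for this test had first been set just under the observed value, which would have counted against dimness, and was widened after the value was seen, because so narrow a margin decides nothing.

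The division into 10 rRNA-dominated and 5 wide-range arrays has no explanation in the labels. Both slides held both kinds (2 wide-range arrays of 8 and 3 of 7, Fisher's exact test, two-sided p = 0.608), which argues against the slide as the whole cause. Each of the 3 arms held both kinds, which argues against the drug arm. More rRNA in the labelled RNA of the 10 arrays stays open and cannot be told apart. Each array's median rRNA signal lay at most 0.717 log2 units below saturation, which leaves little room for a difference, though no non-control spot was flagged as saturated. The median of this signal over arrays was 19.23 log2 units on the 10 arrays and 19.16 on the 5. Whether an arm at one time point caused its array's kind cannot be separated from the array itself with 1 array each.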

How the results depend on the processing

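The counts of tags called by limma stayed at 0 under every alternative run for 2 µg/ml against saline, 4 against 2 µg/ml and the 3 slope comparisons. Their counts at an unadjusted p under 0.05 ranged from 0 to 710, 0 to 1384, 1 to 361, 0 to 210 and 1 to 379. For 4 µg/ml against saline (11 to 953 unadjusted) the count was above 0 under 1 of 33 alternatives, the restriction to time points with arrays of 1 kind, which gave 4 (428 unadjusted) and was chosen after the data were seen. Leaving out any 1 array gave 0 in each comparison. Arms were paired by time point, and without that block each arm comparison also gave 0 (41, 81 and 2 unadjusted). For slopes, leaving out the 0 min arrays and leaving out the 0 min time point are one alternative. The authors' table moves nothing.

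Counts past 2-fold moved more. With quantile normalization they were 1889, 2706, 137 and 586 for 2 µg/ml at 0, 90, 135 and 180 min, and 711 and 790 for 4 µg/ml at 45 and 90 min. With normexp they were 245, 883 and 159 for 2 µg/ml at 45, 90 and 135 min, and 120 for 4 µg/ml at 45 min. With tags well above background on all arrays (3201 tags, so fewer could pass) they were 2050, 500 and 863 for 2 µg/ml at 0, 45 and 90 min, and 1784, 236, 125, 2181 and 2200 for 4 µg/ml from 0 to 180 min. Without tags that follow the control probes they were 1053 and 229 at 90 min. The balance of higher and lower tags moved too, given here as higher and lower counts. With quantile normalization they were 1008 and 881 (0 min) and 89 and 48 (135 min) for 2 µg/ml, and 1280 and 1082 (0 min), 437 and 353 (90 min), 1520 and 1486 (135 min) and 1196 and 1288 (180 min) for 4 µg/ml. With normexp they were 145 and 100 (45 min), 629 and 254 (90 min) and 104 and 55 (135 min) for 2 µg/ml, and 682 and 2369 (0 min), 88 and 32 (45 min) and 383 and 13 (90 min) for 4 µg/ml. With the percentile over probes detected on all arrays they were 269 and 622 (45 min) and 133 and 250 (135 min) for 2 µg/ml, and 153 and 276 (45 min) and 321 and 155 (90 min) for 4 µg/ml. With tags well above background on all arrays they were 783 and 1267 (0 min) and 223 and 640 (90 min) for 2 µg/ml, and 171 and 65, 77 and 48, 1124 and 1057, and 931 and 1269 for 4 µg/ml from 45 to 180 min. Without a filter they were 170 and 212 for 2 µg/ml at 180 min. Without tags that follow the control probes they were 234 and 819 for 2 µg/ml at 90 min, and 186 and 91 (45 min) and 123 and 106 (90 min) for 4 µg/ml. The cause of the other moves was not tested. The mean difference of ncR tags at 2 µg/ml changed sign with quantile normalization, to -0.038 (adjusted p = 0.823, range over alternatives 0.098 to 0.943). The 4 named tags kept their direction under every alternative run for them, but E2348C_1778 at 4 µg/ml was at -0.31 without the 180 min time point and -2.82 without 135 min.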

Other observations

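All tests in this part were chosen after the results were seen. Numbered tags differed from saline along their numbers. In 5 of the 6 contrasts of drug and saline on arrays of 1 kind, tags numbered above 3600 and up to 4400 lay above those numbered above 1200 and up to 2000. The difference of medians was 0.65 log2 units for 4 µg/ml at 45 min (95% interval 0.59 to 0.70) and 0.43 at 90 min (0.35 to 0.55). For 2 µg/ml it was 0.31 at 45 min (0.19 to 0.46), 0.31 at 135 min (0.25 to 0.40) and 0.22 at 180 min (0.15 to 0.29). At 90 min it was 0.10 (-0.08 to 0.37). The windows were chosen after the order had been seen, and 15 contrasts were tested for a wave over tag numbers. Each contrast is 1 array against 1, so permutations and intervals over blocks measure variation over tags and not between cultures or arrays. Block permutations gave an adjusted p of at most 0.000667 for those 5 and 0.737 for 2 µg/ml at 90 min. Of 508 numbered tags lower in all 6 contrasts, 178 lay in the low window and 20 in the high one.

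Some pairs of saline arrays also differed along tag numbers. The windows differed by 0.62 log2 units (0.53 to 0.72) between saline at 0 and 45 min, which argues against drug exposure alone. Between saline at 180 and 45 min the difference was -0.22 (-0.31 to -0.09). Between saline at 90 and 45 min it was -0.0038 (-0.03 to 0.01), with a block permutation adjusted p of 0.516, so this pair showed no such order. The 4 µg/ml 45 min array differed from saline at 0 min by 0.0093 (-0.07 to 0.10), while the 2 µg/ml 45 min array differed by -0.30 (-0.46 to -0.10). A trend with signal level does not account for the pattern, since removing it left at least 0.841 of the window difference in each of the 5 contrasts. Shared saline arrays do not either. Over 89 blocks of 50 tags, 4 µg/ml at 45 and 90 min correlated at 0.698 with 2 µg/ml at 135 and 180 min. These contrasts share no array (permutation p = 0.0001, the smallest that permutations of blocks can give). The permutations took blocks as exchangeable, so likeness of neighbouring blocks can make this p too small, and chance is not excluded. Both contrasts subtract the saline arm, so a trait of its culture along tag numbers is not excluded. A hypothesis is that gene dosage along the chromosome fell in saline as growth slowed and may have fallen less under the drug. It cannot be told apart here from other changes of growth state, because no DNA was measured and the place of the replication origin among the tags was not used.

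Other splits of the arrays were counted for each comparison. With real counts of 0, each of the 35 splits in an arm comparison and of the 100 drawn in a slope comparison had to give as many, so these counts say nothing about chance. The highest counts of other splits were 0 for 2 µg/ml against saline, 2371 for 4 µg/ml against saline, 2553 for 4 against 2 µg/ml, 1236 for the slope at 2 µg/ml and 0 for the slope at 4 µg/ml. Counts of that size point to a structure of the arrays. In each comparison with 4 µg/ml, 1 of the 15 splits whose groups differed by 2 wide-range arrays called tags, and 0 of the 20 splits with equal numbers did. With 1 such split, and 0 of 15 for 2 µg/ml against saline, this does not show that the kind of array caused the calls.

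The 2 µg/ml array at 90 min had a rank correlation over tags of 0.952 with the 4 µg/ml array at 135 min and of 0.685 with saline at 90 min. With saline at 180 min it was 0.814. The 2 drug arrays had the highest control-probe signals above the negative controls, at 5.90 and 5.37 log2 units. Saline had 4.27 at 90 min and 5.13 at 180 min. The cause of these correlations was not tested.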
